A study of Mus musculus with 12 samples.

How the data were processed

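The samples were 12 RNA sequencing libraries from the mouse microglial line N9, in 4 groups of 3 as given by the labels. The authors deposited raw read counts per Ensembl gene, made with featureCounts 1.5.0-p3 on the mm10 build according to the submitters' processing notes. The authors also deposited an FPKM table (fragments per kilobase of gene and scaled library total). Each FPKM value equalled the count divided by the gene length and by 1 constant per library, with a largest deviation of 1.18e-07% among genes with at least 200 counts. The aligner, the annotation release, the strand setting and the trimming of reads are not given in the sources used here. Library preparation was done at a sequencing company per the labels. Every one of the 54532 genes in the count table had an identifier, and gene symbols, biotypes and coordinates were taken from that table, in which 105 symbols were used more than once. Total counts per library were 15453776 to 17956772, and the spread between libraries of a group exceeded counting error, with a lowest ratio of chi-square to degrees of freedom of 3.51 for any pair.

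The counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its default settings, which left 12766, and library sizes were scaled by the trimmed mean of M-values (TMM). A single quasi-likelihood model held all 12 libraries with 1 coefficient per group, leaving 8 residual degrees of freedom per gene. The common dispersion was 0.00496 and the prior degrees of freedom were 8.88. The 4 contrasts tested were LPS in control medium, high glucose under LPS, high fructose under LPS, and high fructose against high glucose under LPS. P-values were adjusted by the Benjamini-Hochberg method within each contrast, and a gene was called at an adjusted p below 0.05. Standard errors came from the quasi-likelihood F statistic. The groups, comparisons, tests, gene lists, naming rule and most alternatives were fixed before the data were examined.

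Genes were named by a rule. For each comparison it took up to 8 called genes with the largest rise and up to 8 with the largest fall among protein-coding genes with a mean of at least 50 counts in either group, a symbol that is not a clone or model name, and no overlap between the 3 libraries of one group and the 3 of the other, a separation that chance gives 10% of genes. A fixed set of 20 genes was added whatever its result, together with up to 4 members of each described list with the smallest adjusted p. Where a list had 5 or fewer called genes, the others were named after their values were seen. For genes with 3 counts or fewer in a group, the ratio of summed counts is given with its 95% counting interval (exact binomial). For genes without a read in a group, a bound is given that takes 3 counts over the group. Intervals and bounds cover counting error only.

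Gene lists were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01. There were 28 lists of biological functions and 7 lists of markers of other cell types, and a list needed 3 tested genes. Listed genes that the filter removed, such as P2ry12, were not tested, so counts and medians cover the tested members only. The lists cover inflammatory cytokines and chemokines, inflammatory effector genes, NF-kB feedback regulators, interferon-stimulated genes, the Toll-like receptor 4 pathway, the inflammasome, antigen presentation, phagocytic and lysosomal genes and immediate early genes. They also cover homeostatic, disease-associated and Alzheimer disease-associated microglia genes, glycolysis, sugar transport and fructose or polyol metabolism, the pentose phosphate pathway, MondoA and ChREBP targets, the tricarboxylic acid cycle, nuclear-encoded oxidative phosphorylation and mitochondrially encoded genes. Fatty acid synthesis, cholesterol synthesis, cholesterol efflux, endoplasmic reticulum chaperones, ATF4 targets, hypoxia-inducible genes, NRF2 targets, cell cycle genes and replication-dependent histones complete the set. The marker lists were neuron, astrocyte, oligodendrocyte, endothelial, fibroblast, epithelial and lymphocyte. Counts of called members are given over all genes tested and adjusted over the list alone. Each camera test was repeated with an estimated correlation and with fry, which asks only whether a list's genes move one way.

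Reads shared between similar genes were checked with BLAST 2.17.0+ against GENCODE M21 transcripts (GRCm38). A gene is reported as uncertain where at least 50% of its longest transcript, or of its main coding transcript, matched another gene at 98% identity over at least 75 bases. Overlap of exons with genes on the other strand was measured on the same annotation, for genes named by size of change or in the fixed set. The main coding transcript was added to this check after the data were seen.

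The high-glucose and high-fructose effects share their control libraries. Their correlation and covariance were computed over genes with an average above 8 CPM and set beside 40 simulated data sets with no sugar effect, drawn with the group means and the fitted dispersions. Each gene and each library was drawn independently. The whole procedure was tested on simulated data with 50 changed genes per fold, drawn only from genes above a minimum mean CPM in control medium with LPS. It recovered 44% to 60% of 1.25-fold changes across the 4 comparisons, 82% to 88% of 1.5-fold changes and 96% to 100% of 2-fold changes. Of the called genes, 3.5% to 5.6% were unchanged ones. The recovery rates do not cover genes with lower counts. In that test camera called the 1 shifted list and 0 of 20 unshifted ones. Its genes were drawn independently, so it says nothing on lists of correlated genes.

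The alternatives tried were DESeq2 size factors, upper-quartile factors and library totals alone in edgeR, no filter and a strict filter (at least 10 counts in 3 libraries and a mean of at least 50), protein-coding genes only, only the 6 libraries compared, the replicate number as a block, each library left out in turn, and glmTreat against a 1.2-fold change. Other tools were DESeq2 1.42.0, limma-voom on counts, and limma on log2 FPKM with pseudocounts of 1 and 0.1 and a minimum of 0.5 in 3 libraries or none. Leaving out genes with similar copies was added after the data were seen. The reads themselves were not used here, and some genes that the naming rule covers are not reported here.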

Results

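RNA sequencing measured gene expression in N9 cells, an immortalised line of mouse microglia, the resident macrophages of the brain. Microglia draw on glucose and other sugars for energy, and lipopolysaccharide (LPS), a component of the outer membrane of Gram-negative bacteria, drives them into an inflammatory state through Toll-like receptor 4. The series concerns sugar use by microglia in Alzheimer disease. Cells were held for 18 h in control medium (3 mM glucose and 5 mM fructose), in medium with 15 mM glucose, or in medium with 15 mM fructose. They were then seeded in wells in the same medium and given LPS at 1 µg/ml for 6 h. There were 4 groups of 3 libraries: control medium without LPS, control medium with LPS, high glucose with LPS, and high fructose with LPS. The labels list no culture with raised sugar but without LPS, and no osmotic control. They do not state whether 15 mM is the final concentration or was added to the control level. No label says that the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

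The authors deposited a raw read count for each of 54532 genes in each library. Total counts per library ran from 16589508 to 17956772 in control medium, from 16363767 to 17015639 in control medium with LPS, from 15919091 to 16743251 with high glucose, and from 15453776 to 16562344 with high fructose. After genes with too few counts were set aside, 12766 genes were tested with edgeR. The first principal component held 46.8% of the variance and separated the libraries with and without LPS, and the next 2 held 9.92% and 7.9%. Libraries of a group stood apart on these, high-glucose library 1 from 2 and 3 on the second (11.9 against −15.8 and −18.5), the high-fructose libraries on it as well (−23.8, 10.9 and −2.01), and high-fructose library 2 from 1 and 3 on the third (32.2 against 9.58 and 6.2). High-fructose libraries 1 and 2 differed by a chi-square of 9.39 per degree of freedom, more than high-fructose and high-glucose library 1 did (8.79). Mitochondrially encoded genes took 0.702 ± 0.085% of counts in control medium (mean ± SD, n = 3), and 0.673 ± 0.084%, 0.635 ± 0.102% and 0.693 ± 0.115% in the LPS groups with control medium, high glucose and high fructose. Genes of ribosomal RNA took 0.451 ± 0.121%, 0.526 ± 0.064%, 0.469 ± 0.114% and 0.367 ± 0.055% in the same order, and their share did not overlap between control medium with LPS (0.585, 0.535 and 0.457%) and high fructose (0.423, 0.313 and 0.365%). Values below are log2 fold changes, given with the standard error (SE) where one is shown, and mean CPM (counts scaled to a common library total) ± SD of 3 libraries. In what follows, control-medium, high-glucose and high-fructose libraries are the LPS-treated ones of those media. A gene is called higher or lower when its adjusted p is below 0.05.

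LPS binding to Toll-like receptor 4 acts through 2 adaptor routes. MyD88 leads to NF-kB and to cytokine genes such as Tnf and Il1b, and TRIF leads to IRF3, type I interferon and the interferon-stimulated genes. Both routes also raise their own inhibitors, and macrophages that respond to LPS shift metabolism and slow division. The first comparison asked how N9 cells responded to LPS in control medium, as the background for the sugar comparisons. LPS raised 1941 genes and lowered 1736, of which 503 and 109 changed at least 2-fold. An unadjusted p below 0.05 was reached by 4836 genes, and the median absolute change of the called genes was 0.41. The split between directions rested on the scaling of the libraries, being 1622 higher and 2292 lower with upper-quartile factors and 1412 and 2951 with library totals alone.

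All 27 tested interferon-stimulated genes, whose products block viral replication, were higher, by 2.03 to 8.01 with a median of 5.44 (camera adjusted p = 6.55e-252; adjusted p = 3.04e-05 with an estimated correlation). Rsad2, which encodes the antiviral enzyme viperin, rose by 7.39 ± 0.12 (SE) from 6.79 ± 1.16 to 1137 ± 73.5 CPM. The RNA-binding Ifit genes rose alongside it, Ifit3b by 8.01 ± 0.20, Ifit3 (ENSMUSG00000074896, chromosome 19 at 34583531 to 34588731 of GRCm38) by 7.20 ± 0.13 and Ifit1 by 7.06 ± 0.15. Oasl1 rose by 4.44 and the nucleotide kinase gene Cmpk2 by 6.69. Cxcl10 (ENSMUSG00000034855, chromosome 5 at 92346638 to 92348889), the chemokine that draws T cells through CXCR3, climbed from 1.56 ± 0.279 to 204 ± 18.1 CPM, a change of 7.03 ± 0.14 (adjusted p = 7.59e-17). Part of Cxcl10, 5.91% of its exonic bases, overlaps a gene on the other strand, and the strand setting of the counts is not given in the sources used here.

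Of the inflammatory cytokines and chemokines, 14 of 15 were higher (median 5.87, or 3.58 with the genes absent in control medium at their bound; camera adjusted p = 6.03e-64; adjusted p = 0.00034 with an estimated correlation). Tnf (ENSMUSG00000024401, chromosome 17 at 35199381 to 35202007) rose by 3.87 ± 0.07, from 15.6 ± 1.54 to 228 ± 4.52 CPM (adjusted p = 3.71e-17). Il1b rose by 5.87, Ccl5 by 6.12 ± 0.26, and the neutrophil chemokine Cxcl2 by 6.59, with Ccl7 at 2.92. Il1a had 821 counts with LPS against 1 without, a ratio of 896 (95% counting interval 160 to 35437), and 11.3% of its exonic bases overlap a gene on the other strand. Il6 was at least 12-fold higher and Cxcl3 at least 9.10-fold, taking 3 counts over the group without LPS, where neither had a read. The collagen gene Col5a3 had 171 counts against 1, a ratio of 187 (33.1 to 7415).

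Inflammatory effector genes were mostly higher, 14 of 16 with 1 lower (median 1.39; camera adjusted p = 2.88e-32; adjusted p = 5.59e-05 with an estimated correlation). Nos2, which makes nitric oxide, rose by 7.93 ± 0.27, from 0.0727 ± 0.063 to 19.8 ± 2.82 CPM. Acod1, the source of itaconate, rose by 4.70, the mitochondrial superoxide dismutase gene Sod2 by 1.48, and the prostaglandin synthase gene Ptgs2 by 1.22. All 19 NF-kB feedback regulators were higher (median 1.47; camera adjusted p = 7.38e-78; adjusted p = 3.04e-05 with an estimated correlation). They included Zc3h12a, whose product degrades cytokine mRNA, at 3.56, the receptor antagonist Il1rn at 2.99, Socs3 at 2.07 and the inhibitor gene Nfkbia at 1.66. Within the receptor pathway itself, 8 of 18 genes were higher and 1 lower, 9 when adjusted over the list alone (median 0.19; camera adjusted p = 0.00158; adjusted p = 0.0251 with an estimated correlation). Tlr2 rose by 1.77, Irak2 by 1.29 and Cd14 by 0.61, and Tlr4 fell by 0.53. Inflammasome genes rose in 7 of 12 cases (median 0.34; camera adjusted p = 1.81e-05; adjusted p = 0.0179 with an estimated correlation), among them Il1b, Casp4 at 2.10 and Nlrp3 at 1.52.

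Antigen presentation genes were higher in 14 of 16 cases (median 0.74; camera adjusted p = 1.40e-16; adjusted p = 0.00453 with an estimated correlation), among them the checkpoint ligand gene Cd274 at 2.09 and the peptide transporter gene Tap1 at 1.78. Of the NRF2 targets, which counter oxidative stress, 10 of 16 were higher and 1 lower (median 0.26; camera adjusted p = 7.73e-07; adjusted p = 0.00453 with an estimated correlation). The cystine transporter gene Slc7a11 rose by 2.31 and Hmox1, for heme oxygenase, by 1.29. Immediate early genes were higher in 7 of 15 cases and lower in 1 (median 0.30; camera adjusted p = 8.75e-05; adjusted p = 0.0241 with an estimated correlation), with Myc at 2.94 and Ier3 at 2.41. The ATF4 target list was called higher, with 8 of 23 genes higher and 1 lower, 9 when adjusted over the list alone (median 0.12; camera adjusted p = 0.00684), but not with an estimated correlation (adjusted p = 0.254). Atf3 rose by 0.88 and Cebpb by 0.97 within it.

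Genes of DNA replication and mitosis fell. Of 27 cell cycle genes, 25 were lower, 26 when adjusted over the list alone (median −0.40; camera adjusted p = 3.95e-10; adjusted p = 0.000529 with an estimated correlation). Rrm2, which supplies deoxynucleotides, fell by 0.53, the helicase gene Mcm7 by 0.57 and the mitotic kinase genes Bub1 and Aurkb by 0.53 and 0.49. Cholesterol synthesis genes were lower in 15 of 19 cases and higher in 1, 16 when adjusted over the list alone (median −0.25; camera adjusted p = 0.000519; adjusted p = 0.101 with an estimated correlation), with Stard4 at −0.49 and Hmgcs1 at −0.35. The genes that fell furthest under the naming rule were Abcd2, a peroxisomal transporter of very long fatty acids (−2.36 ± 0.34), Ipcef1 (−2.23 ± 0.23) and Lbh (−2.23 ± 0.12), which fell from 43.2 ± 4.58 to 9.19 ± 1.19 CPM. Zfp395 followed at −2.17, then the glycogen-targeting subunit gene Ppp1r3c at −1.71, Susd3 at −1.62, Rgs18 at −1.58 and the phosphodiesterase gene Pde1c at −1.58.

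Microglial identity genes went both ways. Of 12 homeostatic microglia genes, 3 were higher and 4 lower, with Mertk, a receptor for dying cells, at −1.31, Mef2c at −0.90 and Selplg at 1.06. Disease-associated microglia genes were higher in 4 and lower in 5 of 19 cases, with Trem2 at −0.53, and Alzheimer disease-associated genes showed the same counts, 4 and 5, among 21. Apoe (−0.68, adjusted p = 0.295) and Cx3cr1 (−0.02, adjusted p = 0.979) did not pass, and leaving out 1 library moved Cx3cr1 from −0.28 to 0.21. P2ry12, with 1 to 6 counts per library, was too low to test. Phagocytic and lysosomal genes were higher in 7 and lower in 4 of 22 cases.

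For energy metabolism, 7 of 20 glycolysis genes were higher and 2 lower. Hk2 rose by 0.72, Hk1 by 0.40 and Ldha by 0.20, and the glucose transporter gene Slc2a1 rose by 0.48 ± 0.04. Among 12 genes of sugar transport and fructose or polyol metabolism, 4 were higher and 3 lower, while Khk, for the kinase that starts fructose breakdown, did not pass (−0.20, adjusted p = 0.18) and the fructose transporter gene Slc2a5 had 0 to 2 counts per library. In the other metabolic lists, 3 of 6 MondoA and ChREBP targets were higher (Txnip 0.39, Arrdc4 0.90), 3 of 10 pentose phosphate genes and 2 of 27 tricarboxylic acid cycle genes were lower, and 1 of 30 oxidative phosphorylation genes was higher. Fatty acid synthesis genes were higher in 4 and lower in 9 of 19 cases, with Acsl1 at 1.01 and Scd1 at −0.81, cholesterol efflux genes higher in 3 and lower in 2 of 11, endoplasmic reticulum chaperones higher in 1 and lower in 6 of 20, and hypoxia-inducible genes higher in 6 and lower in 2 of 15. These metabolic and identity lists were not called by camera. By edgeR 0 of 12 mitochondrially encoded genes were called, against 1 at an unadjusted p below 0.05 and 0 with DESeq2, and 1 of 7 replication-dependent histone genes was lower.

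**Figure D1:**
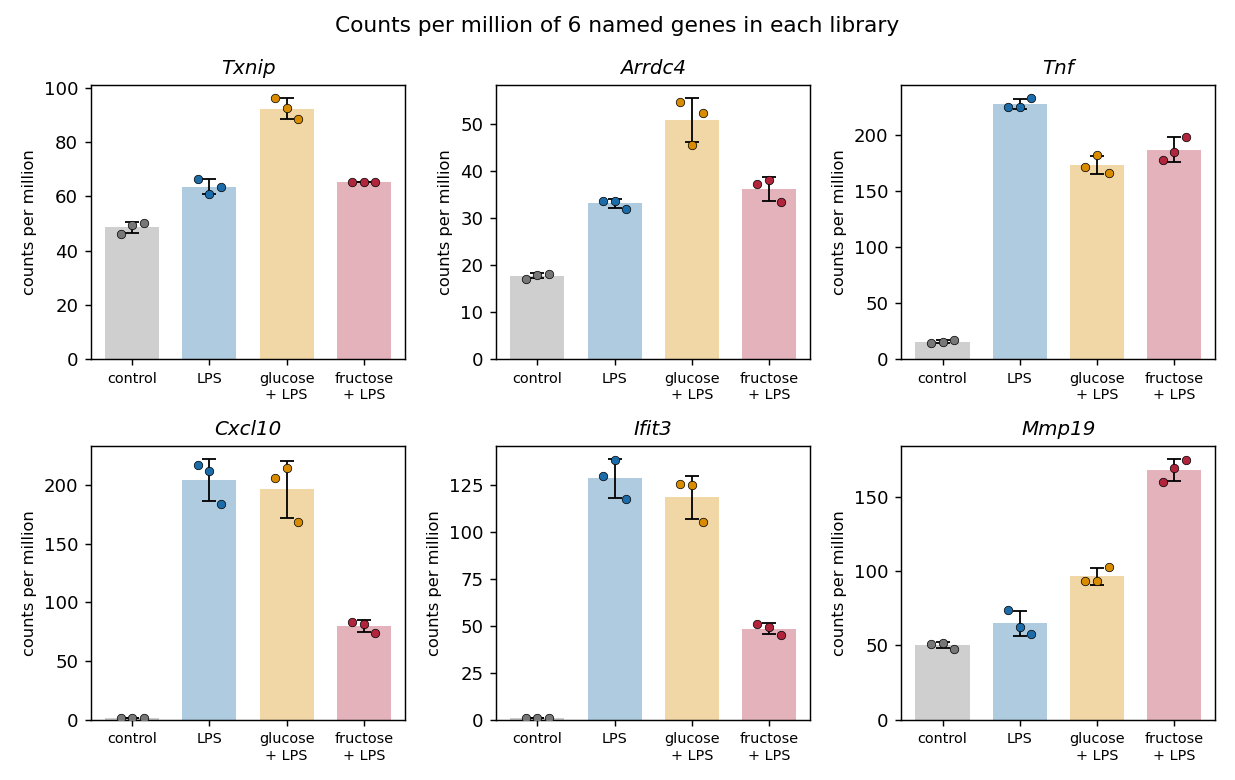
CPM of 6 genes in each of the 12 libraries, with bars for the group mean, error bars for the SD and points for the 3 libraries of a group. Txnip and Arrdc4 stand highest with high glucose and LPS, Cxcl10 and Ifit3 are lower with high fructose and LPS than in the other LPS groups, and Mmp19 is highest with high fructose and LPS.

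The next comparison asked what a rise in glucose before and during LPS changed. Microglia take up glucose through GLUT1 and phosphorylate it with hexokinases. The glucose 6-phosphate that builds up is sensed by MondoA and ChREBP, transcription factors whose best known target is Txnip, an arrestin-like brake on glucose uptake. High glucose is often studied as a source of oxidative stress and of stronger inflammation, as in diabetes. With high glucose, 75 genes were higher and 124 lower than in control medium with LPS, 1 and 2 of them by at least 2-fold. The median absolute change of called genes was 0.31, and 1780 genes had an unadjusted p below 0.05. Leaving out 1 library gave 67 to 177 genes, with 67, 74 and 71 without control-medium libraries 1, 2 and 3 and 70 without high-glucose library 3, and 46 of the 199 genes were called in all 6 such fits. Other settings moved the count both ways, to 427 with no filter, 391 with the replicate number as a block, 328 with DESeq2, and 124, 125 and 93 with limma on log2 FPKM.

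Among the glucose-sensing genes, Txnip and Arrdc4 rose. Txnip (ENSMUSG00000038393, chromosome 3 at 96557957 to 96561883) went from 63.7 ± 2.93 to 92.5 ± 3.89 CPM, a change of 0.54 ± 0.06 (adjusted p = 9.25e-05), although 19.4% of its exonic bases overlap a gene on the other strand. Its relative Arrdc4 rose by 0.62 ± 0.08, from 33 ± 1.00 to 50.8 ± 4.66 CPM (adjusted p = 0.00063). These were the called members of the 6 MondoA and ChREBP targets (median 0.10; camera adjusted p = 9.01e-06; adjusted p = 0.0678 with an estimated correlation). Ogt, which encodes the enzyme that attaches O-linked N-acetylglucosamine, a sugar made from glucose, to proteins, rose by 0.83 ± 0.11 from 37.4 ± 2.66 to 66.6 ± 7.92 CPM (adjusted p = 0.00063). Slc2a1 (0.15, adjusted p = 0.103, or 0.0145 with DESeq2), Hk2 (−0.10), Ldha (0.07) and Khk (0.17) did not pass.

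Other genes with the largest rises under the naming rule included Mmp13, a collagenase (0.98 ± 0.19, 6.70 ± 0.630 to 13.2 ± 0.716 CPM), and the endonuclease gene Ankle1 (0.90). They also included the endothelin gene Edn1 (0.83), Snai1 (0.76), Crtam (0.62) and the metalloproteinase gene Mmp19 (0.58, 64.8 ± 8.22 to 96.6 ± 5.64 CPM, adjusted p = 0.00064). Of the exonic bases of Mmp19, 28.3% overlap genes on the other strand. The largest falls under the naming rule included the survival gene Bcl2 (−0.71), Tifa (−0.68), which links receptors to TRAF6, the calcium pump gene Atp2b4 (−0.67), the mitochondrial folate gene Aldh1l2 (−0.65, adjusted p = 0.00048), the fatty acid receptor gene Gpr84 (−0.64, adjusted p = 0.00154) and Cd28 (−0.59). On the other strand, genes overlap 39.5% of the exonic bases of Gpr84 and 14.1% of those of Aldh1l2. Rps27rt (−1.77) and Gapdh (−3.19, adjusted p = 0.02) are uncertain, since 92.3% and 94.2% of their main coding transcripts match other genes at 98% identity.

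Txnip, Arrdc4, Ogt, Mmp19, Aldh1l2, Gpr84 and Tnf passed the test whichever library was left out. Mmp13 no longer passed without control-medium library 2 or 3 or high-glucose library 3 (adjusted p 0.0554 to 0.0736), Snai1 without control-medium library 1 or 3 (0.0659 and 0.0736), and Tifa without control-medium library 1 (0.0558). Crtam failed without any of the 3 control-medium libraries or high-glucose library 3 (0.0651 to 0.0912), and Edn1 without control-medium library 1 or 2 or high-glucose library 1 or 2 (0.0560 to 0.111). Ankle1 failed without any library but high-glucose 1 (0.0659 to 0.160), Cd28 without any but high-glucose 2 (0.0805 to 0.168), and Atp2b4 without any but high-glucose 2 (0.0623 to 0.119). Bcl2 (0.0505 to 0.115) and Rps27rt (0.0696 to 0.136) failed without any library but control-medium 1.

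Neither list of inflammatory mediators was called. Of 15 cytokines and chemokines 1 was lower, namely Tnf, which fell by 0.40 ± 0.06 from 228 ± 4.52 to 173 ± 7.97 CPM (adjusted p = 0.00202), and the list was not called (camera adjusted p = 0.0797). Il1b (−0.19, adjusted p = 0.775), Il6 (0.31), Cxcl10 (−0.06, adjusted p = 0.832) and Ccl5 (−0.09) did not pass. Cxcl10 ran from −0.13 to 0.04 when 1 library was left out. Of 16 effector genes 1 was higher and 4 lower, 3 and 5 when adjusted over the list alone (camera adjusted p = 0.406). Acod1 was lower (−0.34, adjusted p = 0.00048), as were Cd38 (−0.37) and Cybb, for the phagocyte oxidase (−0.23). Nos2 (0.46, adjusted p = 0.0606) and Ptgs2 (0.20, adjusted p = 0.103) did not pass. Nos2 passed without control-medium library 2 (0.58, adjusted p = 0.0484), with DESeq2 (adjusted p = 0.0276) and with the replicate block (adjusted p = 0.0162).

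By edgeR 0 of 27 interferon-stimulated genes were called over all genes and 0 when adjusted over the list alone, against 9 lower at an unadjusted p below 0.05 and 1 lower with DESeq2. As a list they were called lower (median −0.15; camera adjusted p = 1.57e-05), but not with an estimated correlation (adjusted p = 0.229). NF-kB feedback regulators were called higher, with 3 of 19 higher, or 6 higher and 1 lower when adjusted over the list alone (median 0.07; camera adjusted p = 0.00802; adjusted p = 0.229 with an estimated correlation). These were Il1rn (0.41), Dusp1 (0.36) and Socs3 (0.26), while Nfkbia (0.05) did not pass. Immediate early genes were higher in 3 of 15 cases, 4 when adjusted over the list alone (median 0.16; camera adjusted p = 0.00455; adjusted p = 0.0958 with an estimated correlation), with Fosb at 1.14, Ier3 at 0.36 and Ier5 at 0.27. The immediate early median was 0.06 without control-medium library 3 and 0.08 without high-glucose library 3, the interferon-stimulated median −0.09 without high-glucose library 3, and the feedback median 0.04 without control-medium library 3 and 0.03 without high-glucose library 1.

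NRF2 targets formed the list that held under both settings of camera. They were lower in 3 of 16 cases, 9 when adjusted over the list alone (median −0.15; camera adjusted p = 2.46e-07; adjusted p = 0.0201 with an estimated correlation), with Slc7a11 at −0.58 and Nfe2l2, which encodes NRF2 itself, at −0.28. Prdx1 was also lower (−0.26) but is uncertain, since 68.1% of its transcript matches other genes. Homeostatic microglia genes were lower in 2 of 12 cases, among them Csf1r (−0.29), the receptor on which microglial survival depends, or 5 when adjusted over the list alone (median −0.15; camera adjusted p = 3.42e-05; adjusted p = 0.0799 with an estimated correlation). Disease-associated microglia genes were lower in 3 of 19 cases, 6 when adjusted over the list alone (median −0.11; camera adjusted p = 0.00408; adjusted p = 0.0922 with an estimated correlation). They were Igf1 (−0.37), Cst7 (−0.33) and Gpnmb (−0.12), while Trem2 (−0.04), Apoe (1.02, adjusted p = 0.316) and Cx3cr1 (−1.29, adjusted p = 0.0536) did not pass. Trem2 ran from −0.07 to 0.02 when 1 library was left out, and Cx3cr1 passed without control-medium library 2 (−1.51, adjusted p = 0.0453) and with the replicate block (−1.26, adjusted p = 0.0427). The homeostatic median was −0.09 without high-glucose library 1, and the disease-associated median −0.06 without high-glucose library 3.

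Phagocytic and lysosomal genes were lower in 3 of 22 cases, 5 when adjusted over the list alone (median −0.07; camera adjusted p = 2.43e-05; adjusted p = 0.0811 with an estimated correlation). The inhibitory receptor gene Fcgr2b fell by 0.42, the integrin gene Itgb2 by 0.24 and the lysosomal lipase gene Lipa by 0.21. In cholesterol synthesis 1 of 19 genes was lower, Mvk at −0.31, or 3 when adjusted over the list alone (median −0.10; camera adjusted p = 1.57e-05; adjusted p = 0.0799 with an estimated correlation). Fatty acid synthesis had 1 of 19 lower, Scd2 at −0.22, or 4 when adjusted over the list alone (median −0.04; camera adjusted p = 0.0414; adjusted p = 0.408 with an estimated correlation). Of 16 antigen presentation genes 1 was lower, Tap1 at −0.38 (median −0.10; camera adjusted p = 0.0102; adjusted p = 0.270 with an estimated correlation), and of the 18 receptor pathway genes Tlr2 at −0.23 (median −0.06; camera adjusted p = 0.0329; adjusted p = 0.117 with an estimated correlation), while Tlr4 (−0.08) did not pass. The fatty acid median was −0.07 without high-glucose library 2, and the antigen presentation median −0.06 without control-medium library 1 and −0.06 without high-glucose library 3.

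A further 3 lists were called with 0 of their genes called by edgeR. Cell cycle genes were higher as a list (median 0.05; camera adjusted p = 0.00419; adjusted p = 0.0678 with an estimated correlation), with 4 of 27 higher when adjusted over the list alone, 6 higher and 1 lower at an unadjusted p below 0.05 and 2 higher with DESeq2. Inflammasome genes were lower (median −0.17; camera adjusted p = 0.0170; adjusted p = 0.136 with an estimated correlation), with 2 of 12 when adjusted over the list alone, 5 at an unadjusted p below 0.05 and 0 with DESeq2, and a median of −0.09 without high-glucose library 3. Pentose phosphate genes were lower (median −0.06; camera adjusted p = 0.0344; adjusted p = 0.117 with an estimated correlation), with 2 of 10 by each of these 3 counts. Leaving out 1 library ended 6 of the 15 list calls. The NF-kB feedback call ended without control-medium library 3 or high-glucose library 1 (0.0806 and 0.101), and the inflammasome and antigen presentation calls without control-medium library 1 or high-glucose library 3 (0.0795 and 0.0986, and 0.0574 and 0.112). The receptor pathway call ended without control-medium library 3 or high-glucose library 1 or 3 (0.0510 to 0.0899), the fatty acid call without control-medium library 1 or high-glucose library 1 or 3 (0.0863 to 0.111), and the pentose phosphate call without control-medium library 1 or 2 or high-glucose library 2 or 3 (0.0539 to 0.0728).

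The remaining lists were not called. Among 20 glycolysis genes only the uncertain Gapdh was called, so the list mean (−0.15) and median (0.02) differ in sign. For the other 19 genes, values ran from −0.13 to 0.14, edgeR called 0, an unadjusted p below 0.05 was reached by 3 and DESeq2 called 0. Sugar transport had Slc2a6 lower (−0.30) among 12, the tricarboxylic acid cycle Idh1 (−0.28) among 27, ATF4 targets Slc7a11 among 23, and Alzheimer disease-associated genes Ptk2b (−0.20) among 21. By edgeR 0 genes were called among 30 for oxidative phosphorylation, 12 mitochondrially encoded, 11 for cholesterol efflux, 20 chaperones, 15 hypoxia-inducible genes and 7 histones. At an unadjusted p below 0.05 these lists had 0, 1, 3, 3, 3 and 1 genes, and with DESeq2 0, 0, 1, 0, 1 and 0.

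High fructose was the other sugar tested. Fructose enters cells through GLUT5 and, where ketohexokinase is present, is phosphorylated past the main control point of glycolysis, and hexokinases can also use it. Slc2a5, for GLUT5, was close to absent here, with 0 to 2 counts per library. The comparison asked what raised fructose changed in LPS-treated cells. With high fructose, 302 genes were higher and 325 lower than in control medium with LPS, 17 and 36 of them by at least 2-fold. Called genes had a median absolute change of 0.36, and 1984 genes had an unadjusted p below 0.05. Leaving out 1 library gave 426 to 535 genes, and 338 of the 627 were called in all 6 such fits.

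Interferon-stimulated genes fell. Of 27 members 25 were lower, 26 when adjusted over the list alone (median −1.03; camera adjusted p = 1.23e-148; adjusted p = 0.000197 with an estimated correlation). Ifit3 fell by 1.41 ± 0.08, from 129 ± 10.5 to 48.5 ± 2.96 CPM (adjusted p = 5.56e-09), and Ifit2 by 1.48 ± 0.08, from 326 ± 11.7 to 117 ± 13.6 CPM. Mx1, whose product traps viral nucleocapsids, fell by 1.75, Ifi44 by 1.71, Ifit1bl2 by 1.46, Slfn8 by 1.42 and Ifit1 by 1.33. The RNA-sensing gene Oasl2 fell by 1.08 and Irf7, the transcription factor gene that amplifies interferon production, by 0.93. In control medium without LPS, Ifit3 had stood at 0.870 ± 0.111 CPM and Oasl2, which LPS raised by 5.18, was likewise far lower.

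Cytokines and chemokines were called lower as a list, with 4 of 15 lower, or 7 lower and 1 higher when adjusted over the list alone (median −0.20; camera adjusted p = 1.52e-08; adjusted p = 0.0764 with an estimated correlation). Cxcl10 fell by 1.36, from 204 ± 18.1 to 79.6 ± 5.15 CPM (adjusted p = 3.39e-08), the monocyte chemokine genes Ccl7 and Ccl2 by 0.75 and 0.61, and Tnf by 0.29 ± 0.06, to 187 ± 10.8 CPM (adjusted p = 0.00571). Il1b (0.33), Il6 (0.43) and Ccl5 (−0.46, adjusted p = 0.085) did not pass, and Il6 ran from −0.22 to 0.85 when 1 library was left out. Ccl5 passed without high-fructose library 1 (−0.66, adjusted p = 0.0118) and with the replicate block (−0.48, adjusted p = 0.00697). Of 16 effector genes 5 were lower, or 7 lower and 2 higher when adjusted over the list alone (median −0.17; camera adjusted p = 0.00239; adjusted p = 0.0618 with an estimated correlation). These included Cd38 (−0.58), Cybb (−0.54), Acod1 (−0.19) and Nos2, which fell by 0.59 from 19.8 ± 2.82 to 13.2 ± 1.22 CPM (adjusted p = 0.00669). Nos2 no longer passed without control-medium library 2 (−0.46, adjusted p = 0.0608), and the effector median was −0.09 without control-medium library 1. Ptgs2 (0.17) did not pass.

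Antigen presentation genes were lower in 8 of 16 cases, 12 when adjusted over the list alone (median −0.25; camera adjusted p = 1.55e-13; adjusted p = 0.0173 with an estimated correlation). Tap1 fell by 0.86, Cd274 by 0.51, the immunoproteasome gene Psmb10 by 0.41 and Tapbp by 0.31. Phagocytic and lysosomal genes were lower in 5 of 22 cases (median −0.10; camera adjusted p = 8.72e-06; adjusted p = 0.0618 with an estimated correlation), among them the antibody receptor genes Fcgr1 (−1.10), Fcgr4 (−0.78) and Fcgr2b (−0.58), and Lipa (−0.24). Cell cycle genes were lower in 2 of 27 cases, Rrm2 (−0.30) and Mcm4 (−0.25), or 8 when adjusted over the list alone (median −0.11; camera adjusted p = 0.000209; adjusted p = 0.0173 with an estimated correlation).

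Some NF-kB feedback regulators were higher, 4 of 19, Dusp1 (0.43), Traf1 (0.36), Nfkbiz (0.31) and Socs3 (0.27), while Nfkbia (0.12) did not pass (median 0.08; camera adjusted p = 0.00347; adjusted p = 0.264 with an estimated correlation), and the call ended without control-medium library 3 (adjusted p = 0.0540). The median was 0.05 without that library and 0.05 (0.045) without high-fructose library 1. In the receptor pathway edgeR called 0 of 18 genes and DESeq2 0, with 2 at an unadjusted p below 0.05, and Tlr4 stood at 0.12. In the inflammasome list edgeR called 0 of 12 and DESeq2 0, with 3 at an unadjusted p below 0.05. Immediate early genes were higher in 2 of 15 cases, Nr4a2 (0.57) and Ier3 (0.54), and the list was not called.

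Under the naming rule, the largest rises with high fructose were in Tnfaip6 (1.70), which makes a hyaluronan-binding protein of resolving inflammation, and the water channel gene Aqp1 (1.63). Next came Mmp19, the annexin gene Anxa8 (1.38), Tubb3, Olfml3 (1.08), Edn1 (1.08) and A4galt (1.06), for a glycolipid synthase. Some called genes with fewer counts than the rule asks rose further. Mmp19 (ENSMUSG00000025355, chromosome 10 at 128790910 to 128800824) rose by 1.38 ± 0.07, from 64.8 ± 8.22 to 168 ± 7.54 CPM (adjusted p = 5.56e-09), with 28.3% of its exonic bases overlapped on the other strand. Tubb3, a tubulin gene also used as a neuron marker, rose by 1.27 ± 0.12 from 12.7 ± 1.74 to 30.6 ± 2.09 CPM. It was the called member of the 3 tested neuron markers (median 0.74; camera adjusted p = 0.000921; adjusted p = 0.0618 with an estimated correlation), and it had also risen with LPS alone (1.66). The median of the 3 was 0.05 without high-fructose library 2, 1.16 without high-fructose library 1 and 0.42 without control-medium library 3.

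Txnip (0.04, adjusted p = 0.830) and Arrdc4 (0.13, adjusted p = 0.490) did not pass with high fructose, and edgeR and DESeq2 each called 0 of the 6 MondoA and ChREBP targets, with 0 at an unadjusted p below 0.05. Slc2a1 (0.13, adjusted p = 0.0859, or 0.0202 with DESeq2), Hk2 (−0.09), Ldha (0.04) and Khk (0.15) did not pass. Hk1 was the 1 called of 20 glycolysis genes (0.19), and in sugar transport and polyol metabolism Akr1b8 was higher (0.20) and Slc2a6 lower (−0.32), beside Akr1b3 (0.28), which is uncertain because 97.5% of its transcript matches other genes. Of 16 NRF2 targets 2 were higher, Sqstm1 (0.29) and Srxn1 (0.22), and 1 lower, Nfe2l2 (−0.24). By edgeR 0 genes were called among 27 of the tricarboxylic acid cycle, 30 of oxidative phosphorylation, 12 mitochondrially encoded, 10 of the pentose phosphate pathway, 20 chaperones and 7 histones. At an unadjusted p below 0.05 these lists had 1, 0, 0, 2, 4 and 0 genes, and with DESeq2 1, 0, 0, 0, 0 and 0.

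In lipid metabolism Acly was higher (0.27) and Plin2 (−0.23) and Scd2 (−0.15) lower among 19 fatty acid genes, Insig1 (−0.20) and Dhcr7 (−0.18) were lower among 19 cholesterol synthesis genes, and Smpdl3a was higher (0.48) among 11 of cholesterol efflux. Ndrg1 rose (0.61) among 15 hypoxia-inducible genes and Atf3 fell (−0.44) among 23 ATF4 targets. Homeostatic microglia genes were higher in 2 and lower in 3 of 12 cases, with Olfml3 (1.08) and Selplg (0.22) up and Csf1r (−0.20) and Mef2c (−0.21) among those down. Of 19 disease-associated microglia genes 3 were lower, and of 21 Alzheimer disease-associated genes 3 were lower, Clu (−0.55), Psen2 (−0.21) and Ptk2b (−0.17). Trem2 (0.06), Cx3cr1 (−0.56) and Apoe (1.43, adjusted p = 0.0795) did not pass. Apoe had 458, 120 and 114 counts in the high-fructose libraries, and passed without library 2 (1.74, adjusted p = 0.0230) or 3 (1.73, adjusted p = 0.0330). Camera called none of these 8 lists.

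**Figure D2:**
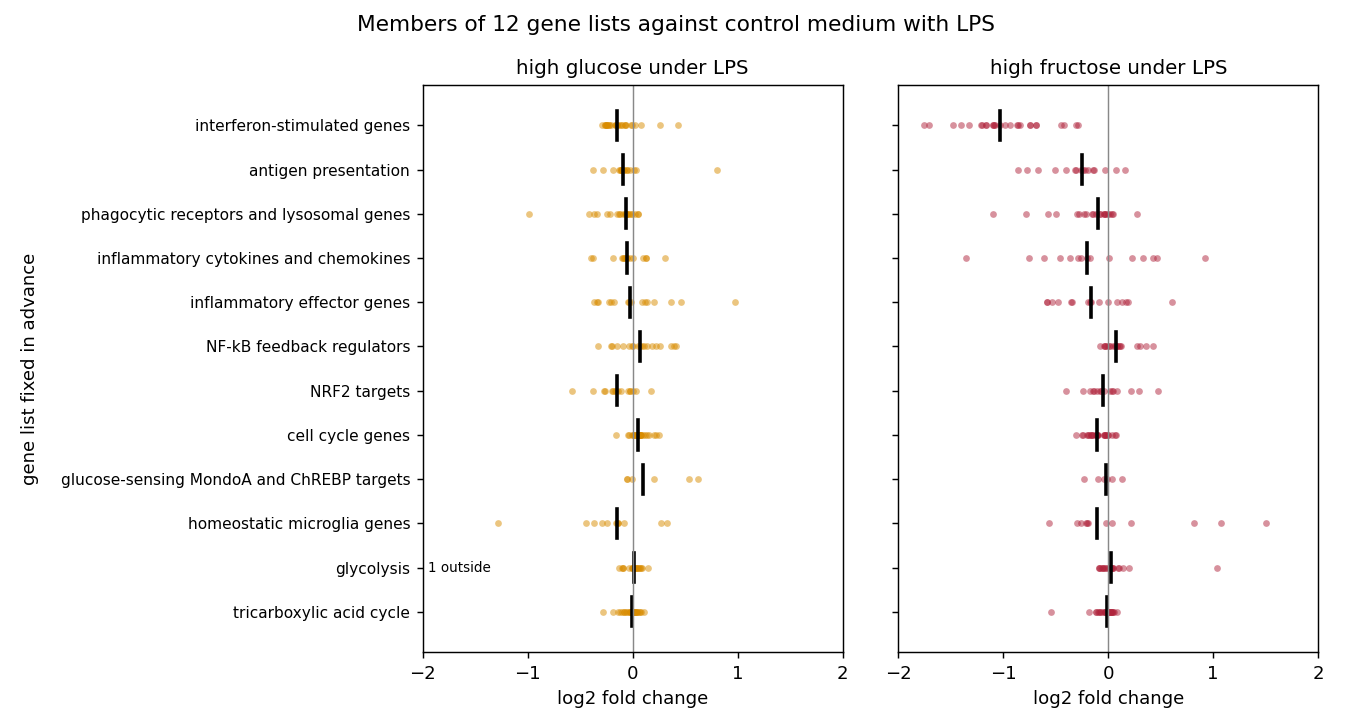
Log2 fold changes of the tested members of 12 gene lists, each point a gene and each black bar the median, with high glucose and LPS and with high fructose and LPS, both against control medium with LPS. Interferon-stimulated genes lie around −1.03 with high fructose and −0.15 with high glucose, and 1 glycolysis gene lies outside the axis with high glucose.

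A call with one sugar and not with the other does not show a difference, so both sugars were also compared directly under LPS. Glucose and fructose have the same formula and part at transporters, at the first kinase and at glucose sensing. The media differed in both sugars at once, 15 mM glucose with 5 mM fructose against 3 mM glucose with 15 mM fructose if these are final levels. A difference can therefore not be assigned to one sugar. If these are final levels, which the labels do not state, the rise in osmolarity was also not equal. High fructose gave 235 genes higher and 240 lower than high glucose, 6 and 22 of them by at least 2-fold. The median absolute change of called genes was 0.33, and 1995 genes had an unadjusted p below 0.05. Leaving out 1 library gave 332 to 385 genes, and 221 of the 475 were called in all 6 such fits. The replicate block gave 735 genes, and the 6 libraries compared alone gave 247.

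Interferon-stimulated genes were lower with fructose than with glucose in 24 of 27 cases, 26 when adjusted over the list alone (median −0.85; camera adjusted p = 1.55e-126; adjusted p = 0.000433 with an estimated correlation). Ifit3 differed by −1.29 (adjusted p = 6.9e-08), Ifit2 by −1.24, Rsad2 by −1.11, Cmpk2 by −1.15, Mx1 by −1.49 and Ifi44 by −1.55. Ifit1bl2 (−1.31) and Ifit1bl1 (−1.24), further members of the Ifit cluster, went with them. Apol9b (−1.27) is uncertain, since its whole main coding transcript matches another gene. Cytokines and chemokines were lower in 3 of 15 cases, 4 when adjusted over the list alone (median −0.09; camera adjusted p = 1.50e-05; adjusted p = 0.147 with an estimated correlation), with Cxcl10 at −1.30 ± 0.09 (adjusted p = 1.4e-07), Ccl7 at −0.65 and Ccl2 at −0.54. That median was 0.03, −0.01 and −0.22 without high-glucose libraries 1, 2 and 3, and −0.03 without high-fructose library 1, so its sign rests on high-glucose library 1. Tnf did not differ detectably (0.11, adjusted p = 0.394), nor did Il1b (0.52), Ccl5 (−0.37) or Nfkbia (0.07), although Ccl5 passed without high-fructose library 1 (−0.56, adjusted p = 0.0404) and with the replicate block (adjusted p = 0.0364). Antigen presentation genes were lower in 5 of 16 cases, 6 when adjusted over the list alone (median −0.21; camera adjusted p = 5.50e-08; adjusted p = 0.0661 with an estimated correlation), with Tap1 at −0.48, Cd274 at −0.32, Psmb10 at −0.28 and Tapbp at −0.22.

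Nos2 was lower with fructose by 1.04 ± 0.12, at 13.2 ± 1.22 against 27.1 ± 0.877 CPM (adjusted p = 4.6e-05). Of 16 effector genes 1 was higher, Ncf1 (0.18), and 2 lower, Nos2 and Cybb (−0.31), or 3 and 5 when adjusted over the list alone (median −0.11; camera adjusted p = 0.0220; adjusted p = 0.143 with an estimated correlation), a call that ended without high-glucose library 2 (adjusted p = 0.0501) and whose median was −0.03 without high-fructose library 1. Fcgr1 was lower by 1.09 and Itgb2 higher by 0.29 among phagocytic genes, Il1rn (−0.33), Zfp36 (−0.23) and Dusp2 (−0.47) were lower among NF-kB feedback regulators, and neither list was called. Receptor pathway genes were called higher with 1 of 18 higher, Tlr2 at 0.20, or 3 when adjusted over the list alone (median 0.05; camera adjusted p = 0.0389; adjusted p = 0.143 with an estimated correlation), while Tlr4 did not pass (0.20, adjusted p = 0.0906). That call ended without high-glucose library 1 or 3 or high-fructose library 2 (0.0620 to 0.253), and its median was 0.08 without high-fructose library 1 and 0.10 without library 3.

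Txnip and Arrdc4 differed between the sugars. Txnip was lower with fructose by 0.50 (adjusted p = 2.9e-05) and Arrdc4 by 0.49 (adjusted p = 0.00114), the 2 called of 6 MondoA and ChREBP targets, or 3 when adjusted over the list alone (median −0.24, or −0.43 without high-fructose library 2; camera adjusted p = 2.99e-05; adjusted p = 0.0661 with an estimated correlation). NRF2 targets were higher with fructose in 3 of 16 cases, 4 when adjusted over the list alone (median 0.09; camera adjusted p = 1.83e-05; adjusted p = 0.0233 with an estimated correlation), namely Slc7a11 (0.44), Sqstm1, for an autophagy receptor (0.31), and Srxn1 (0.24). Cell cycle genes were lower in 8 of 27 cases, 19 when adjusted over the list alone (median −0.17; camera adjusted p = 3.40e-12; adjusted p = 0.000561 with an estimated correlation), with Aurkb at −0.28, Rrm2 at −0.26, Mcm4 at −0.24 and Mcm3 at −0.23. Slc2a1 (−0.01), Khk (−0.03), Hk2 (0.01), Ldha (−0.03), Ptgs2 (−0.03), Il6 (0.12) and Apoe (0.41) did not pass, and each took both signs when 1 library was left out. Of 20 glycolysis genes the uncertain Gapdh was called (4.23). By edgeR 0 of 27 tricarboxylic acid cycle genes and 0 of 30 for oxidative phosphorylation were called, with 1 in each list at an unadjusted p below 0.05 and 0 in each with DESeq2.

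Higher with fructose were Aqp1 (1.33), Anxa8 (1.10), Tubb3 (1.08), Atp2b4 (1.05), the tubulin-binding gene Tppp3 (0.89), Mmp19 (0.80) and the focal adhesion gene Tns1 (0.68). Tppp3 did not pass without high-glucose library 2 or 3 or high-fructose library 2 or 3 (adjusted p 0.0745 to 0.120), nor Tns1 without any library but high-fructose 1 (0.0539 to 0.176), and Tns1 stood at 0.43 without high-fructose library 2. Neuron markers were called through Tubb3, 1 of 3 (median 0.16; camera adjusted p = 0.00246; adjusted p = 0.0661 with an estimated correlation), a call that ended without high-fructose library 2 (0.0508). Their median was 0.08, 0.10 and 0.29 without high-glucose libraries 1, 2 and 3 and 0.26, 0.01 and 0.24 without high-fructose libraries 1, 2 and 3. Homeostatic microglia genes were called higher with 1 of 12 higher, Selplg at 0.36, or 2 when adjusted over the list alone (median 0.13; camera adjusted p = 0.0110; adjusted p = 0.201 with an estimated correlation). Without high-glucose library 1 or 2 or high-fructose library 1 or 2 this call ended (0.0501 to 0.20), and the median was 0.09 without high-glucose library 3 and 0.08 without high-fructose library 1. Among disease-associated genes Cd9 was higher (0.24), Clu was lower among Alzheimer disease-associated genes (−0.57), Ndrg1 was higher among hypoxia-inducible genes (0.42), and Trem2 (0.10) and Cx3cr1 (0.72) did not pass.

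The high-glucose and high-fructose comparisons used the same 3 control-medium libraries, so their errors were shared. Across 9218 genes, which are not independent replicates, the log2 fold changes of both sugars correlated at r = 0.588, and 40 simulations with no sugar effect gave a median of 0.495 (0.473 to 0.528). Spearman's correlation was 0.461 against a simulated 0.471. The covariance was 0.0178 against a simulated 0.00488, an excess of 0.0129. Both sugars raised 43 genes and lowered 57. Independent calls in these numbers would share 1.77 and 3.16 by chance, but the shared controls make the calls dependent. The simulations gave 0 and 0 (at most 1 and 0), which is no benchmark, since few genes are called with no sugar effect. EdgeR called 0 genes in opposite directions, against 28 at an unadjusted p below 0.05 and 3 with DESeq2. How far shared errors add to the overlap when both sugars act was not simulated, nor was the likeness between libraries of the same number. Genes raised in both included Mmp19 and Edn1, and genes lowered in both included Tnf, Fcgr2b, Csf1r and Nfe2l2. Without high-fructose library 1 the correlation was 0.416 and the covariance 0.0102.

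The 503 genes that LPS had raised at least 2-fold were then followed. With high fructose 142 were lower and 37 higher, with a median of −0.21 against a simulated −0.02. With high glucose 19 were lower and 14 higher, with a median of −0.05 against a simulated −0.02. The 109 genes that LPS had lowered stood at 0.11 with high glucose (simulated 0.15) and 0.19 with high fructose (simulated 0.14), both inside the simulated ranges of 0.10 to 0.23 and 0.07 to 0.21. The strict filter turned both, to −0.17 and −0.13. With high glucose the raised genes stood at −0.08 without control-medium library 1, and the lowered genes at 0.06 and 0.05 without control-medium libraries 2 and 3. Without library 2 or 3 of control medium without LPS, the lowered genes stood at 0.04 and 0.04 with high glucose, and without its library 2 at 0.11 with high fructose.

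**Figure D3:**
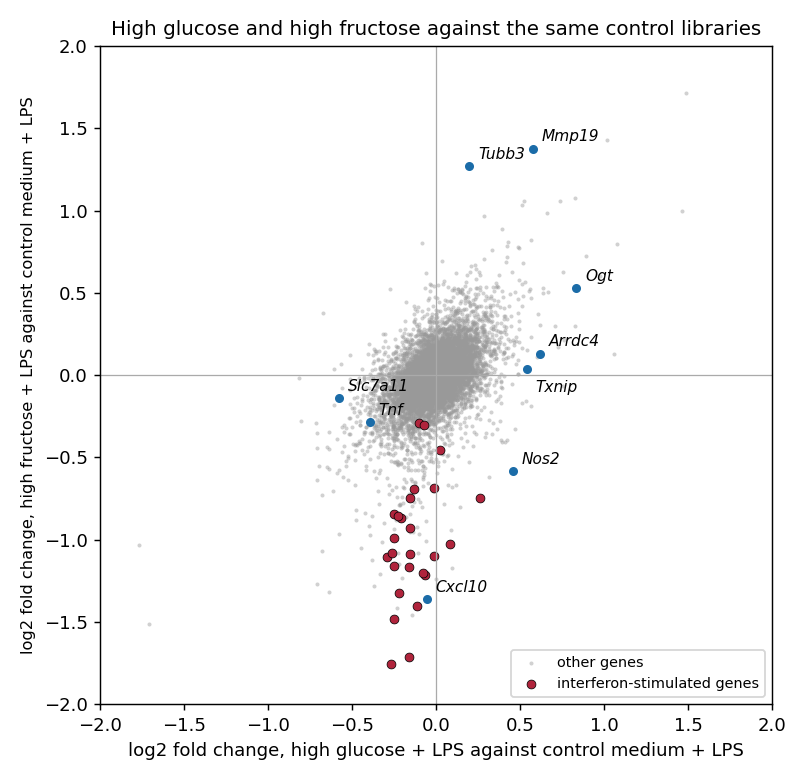
Log2 fold changes with high glucose and LPS (horizontal) and with high fructose and LPS (vertical), both against control medium with LPS, for 10404 genes with a mean of at least 3 CPM, of which 2 lie outside the axes. Interferon-stimulated genes, in red, lie below 0 on the vertical axis and near 0 on the horizontal one, and named genes are in blue.

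Markers of other cell types were tested for reads from other cells. With LPS, Tubb3 rose and Map2 fell (−0.42) among 3 neuron markers, Gja1 rose (0.17) and Aldh1l1 fell (−0.30) among 3 astrocyte markers, and Kdr (2.24) and Cdh5 (1.51) rose and Flt1 fell (−0.36) among 4 endothelial markers. Vwf was lower with high glucose (−0.51) and Gja1 higher with high fructose (0.30). Of 4 fibroblast markers edgeR and DESeq2 called 0 in any comparison, with 1 at an unadjusted p below 0.05 with high fructose and 0 in the others. Their medians were −1.27 with LPS, −0.02 with high glucose, 2.01 with high fructose and 2.03 between the sugars, and camera did not call the list (adjusted p = 0.602, 0.565, 0.137 and 0.207). Dcn (2.36) was higher with high fructose when adjusted over the list alone. Counts differed widely between libraries of a group, with Col1a1 at 70, 3 and 49 in control medium, 40, 3 and 1 with LPS, 1, 1 and 41 with high glucose, and 59, 114 and 3 with high fructose. Reads from other cells in some of the libraries were therefore not excluded. Oligodendrocyte, epithelial and lymphocyte markers had 2, 2 and 0 tested genes and were not tested as lists.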

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

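One alternative, leaving out genes with near-identical copies, was chosen after the data were seen, and gave 3652, 234, 676 and 510 called genes for LPS, high glucose, high fructose and fructose against glucose. The number of called genes stayed within 1.5 times of that reported in every comparison with DESeq2 size factors, upper-quartile factors, library totals, the strict filter, limma-voom and protein-coding genes alone. For each sugar against control medium the scalings left the median of all genes between −0.0077 and 0.0086, so steady counts there say nothing on scaling. For LPS the split still moved, from 1941 higher and 1736 lower to 1412 and 2951 with library totals. Requiring more than a 1.2-fold change left 1565, 3, 147 and 65 genes, as a stricter test must. The high-glucose count of 199 was the least steady, at 427 with no filter, 391 with a replicate block, 328 with DESeq2, 124 and 125 with limma on log2 FPKM with pseudocounts of 1 and 0.1, and 93 without a minimum. Without 1 library it was 67 to 177, and fewer libraries alone can lower it. Fructose against glucose gave 735 genes with the block and 247 from only the 6 libraries compared, which leaves fewer degrees of freedom. The cause was not tested for the other changes. Without 1 library the LPS, high-fructose and fructose-against-glucose counts were 2992 to 3175, 426 to 535 and 332 to 385.

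Libraries with the same number in different groups resembled each other after group means were removed. Of 18 such pairs, 13 correlated above 0.1 (−0.005 to 0.295). For 11 of 12 libraries the mean correlation with libraries of other groups was highest for their own number. The labels pair nothing, so the block was kept as an alternative. It gave 4149 and 847 genes for LPS and high fructose, and all 45 list calls held with it.

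Of the lists called, 17 of 45 held with an estimated correlation and 42 with fry. The estimated correlation left 1 list for high glucose, 3 for high fructose and 3 for fructose against glucose, against 15, 8 and 10, and fry called 24 for LPS against 12. The cause was not tested. With each library left out in turn, 26 list calls ended and 244 held. The 84 calls of named genes all held with DESeq2 size factors, the DESeq2 test and the block. Limma on log2 FPKM did not test 2 and ended 7 (Ankle1, Rps27rt, Bcl2, Atp2b4 and Cd28 with high glucose, Olfml3 with high fructose, Tns1 between the sugars), and leaving out 1 library ended 49 and kept 455, with no called gene changing sign. Uncalled named genes also came to pass, 4 with the block (Nos2 and Cx3cr1 with high glucose, Ccl5 with high fructose and between the sugars), 3 with DESeq2 (Slc2a1 with each sugar, Nos2 with high glucose), and 6 with 1 library left out (the block genes without 1 library each, Apoe with high fructose without either of 2).

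Genes lowered by LPS moved the other way under the strict filter, at −0.17 with high glucose and −0.13 with high fructose, and the cause was not tested. With 1 library left out, some uncalled genes took both signs. These were Cx3cr1 with LPS (−0.28 to 0.21), Cxcl10 (−0.129 to 0.042) and Trem2 (−0.073 to 0.022) with high glucose, and Il6 with high fructose (−0.22 to 0.85). Between the sugars they were Slc2a1 (−0.029 to 0.005), Khk (−0.12 to 0.10), Hk2 (−0.067 to 0.087), Ldha (−0.058 to 0.016), Il6 (−0.53 to 0.55), Ptgs2 (−0.066 to 0.005) and Apoe (−0.55 to 0.95). Depth limits the low genes, since P2ry12 and Slc2a5 had too few counts to test, and small changes near the spread between libraries were often missed in simulated data.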

Other observations

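The test of main coding transcripts, the test of the other glycolysis genes, the test of a weaker LPS stimulus, and the gene families and single genes described last were chosen only after the results were seen.

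Interferon-stimulated genes were lower with high fructose and LPS, by a median of 1.03 on the log2 scale. A single library did not decide it, since the median reached at most −0.98 when any 1 of the 6 libraries was left out. Library totals and upper-quartile factors gave at most −1.02 but left the median of all genes between −0.0077 and 0.0017, so these alternatives tested nothing. Scaling, however, shifts all genes of a library alike. In the reported fit the median of all genes was −0.0013 and that of NF-kB feedback genes 0.075. These values argue against scaling as the source of the gap between interferon-stimulated and other genes. An LPS stimulus weakened alike for all genes is argued against too, as LPS-induced NF-kB feedback genes lost a median of −4.61% of their log2 LPS response, that is, gained (quartiles −7.62 to 0.09), against losses of 19.4% (14.4 to 26.1) for interferon-stimulated genes, 29.0% for antigen presentation, 8.71% (−6.88 to 19.8) for effector genes and 5.62% (−5.10 to 12.4) for cytokines. A lower dose that spares genes already near their maximum stays open, and how fructose would act on these genes was not tested.

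Gapdh and Rps27rt were lower with high glucose, and their counts varied within groups too, with Gapdh at 2009, 185 and 3558 in the control-medium LPS libraries and 175, 227 and 211 with high glucose. A shared change in the expression of glycolysis genes is argued against, because the median of the other 19 glycolysis genes was 0.026. Neither glycolytic activity nor a change of Gapdh alone was tested. Reads shared with gene copies are a candidate explanation. At least 92.3% of the main coding transcript of each matched other genes. Only 35.7% of the longest Gapdh transcript did, with matches to 74 other genes, which by itself left the question open. Why reads would be shared differently between libraries was not tested.

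Both sugars moved many genes alike. The covariance was 0.0178, above the highest of 40 simulated values (0.00560). Spearman's correlation of 0.461 lay inside its simulated range (0.452 to 0.488). The simulations drew every gene and library independently, while the real libraries of the same number resembled each other. They therefore cannot decide whether chance values of the shared control libraries account for the likeness. Raised osmolarity may have contributed and cannot be told apart from raised sugar, as no osmotic control is listed. The median of 11 tested osmotic-response genes was 0.084 with high glucose and 0.185 with high fructose. Of these, 3 were called higher with high fructose, Slc6a12 (0.33), Slc38a2 (0.29) and Akr1b3 (0.28, uncertain for its copies), and 0 with high glucose by edgeR, against 5 at an unadjusted p below 0.05 and 2 with DESeq2.

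When the 6 libraries of a comparison were split in each of 10 ways, 1 split, the real one, gave the most genes in each comparison. The real and the highest other counts were 4221 and 0 for LPS, 147 and 0 for high glucose, 561 and 5 for high fructose, and 247 and 5 for fructose against glucose. The splits are too few for a share under 0.05.

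Interferon-inducible GTPases, which attack the vacuoles of intracellular microbes, followed the interferon-stimulated genes. Gbp2, Gbp3 and Gbp5 belong to both, so the GTPases are not a separate set. With LPS 11 of 11 tested members were higher (median 3.63), and with high fructose 9 were lower (median −1.08) and 8 were lower than with high glucose (median −0.83). Gvin1, 1 of the 11, is uncertain, since all of its transcript matches other genes. These counts were the same with DESeq2 size factors, upper-quartile factors and library totals. In the sugar comparisons these scalings hardly moved the median of all genes (−0.0077 to 0.0017 with high fructose). Unchanged counts there, for this family and those below, therefore tested nothing. Gbp2 fell by 1.10 with high fructose, Gbp3 by 1.17, Gbp7 by 1.23, Igtp by 0.94 and Irgm1 by 0.74, and Iigp1 fell from a mean of 27.7 to 4.67 counts. With high glucose edgeR called 0 of 11, against 3 at an unadjusted p below 0.05 and 0 with DESeq2. The transcription factor genes Irf8 and Irf5, which set macrophage identity and inflammatory programmes, were lower with both sugars, at −0.30 and −0.22 with high glucose and −0.33 and −0.32 with high fructose.

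Enzymes that add and remove O-linked N-acetylglucosamine moved apart with high glucose, Ogt at 0.83 and the O-GlcNAcase gene Mgea5 at −0.39 (edgeR adjusted p = 0.0062). With high fructose Ogt rose by 0.53, and Mgea5 did not pass (−0.15, edgeR adjusted p = 0.28). Between the sugars neither gene passed, with Ogt at −0.30 (edgeR adjusted p = 0.131) and Mgea5 at 0.24 (edgeR adjusted p = 0.0574). Annexins, which bind membranes in the presence of calcium, were higher with fructose than with glucose in 6 of 10 cases under each of the 4 scalings (median 0.24), among them Anxa1 (0.55 ± 0.05, SE), a mediator of resolving inflammation, Anxa2 (0.38), Anxa6 (0.39) and Anxa8 (1.10). Against control medium 3 were higher and 1 lower with high fructose and 0 higher and 1 lower with high glucose, Anxa3 being lower with each (−0.30). LPS had raised 8 of them, or 7 with upper-quartile factors or library totals. Heterogeneous nuclear ribonucleoprotein genes were higher with high glucose in 3 of 20 cases, Hnrnpdl (0.32), Hnrnpl (0.25) and Hnrnpa1 (0.26). Hnrnpa1 is uncertain, since 50.3% of its main coding transcript matches other genes, as are 3 uncalled members. Lower with fructose than with glucose were 3 of the 20, or 4 with library totals. LPS had lowered 4 of these genes, or 5 with upper-quartile factors and 6 with library totals. With high fructose edgeR and DESeq2 called 0 of them, with 2 at an unadjusted p below 0.05. Collagen genes were higher with high fructose in 4 of 16 cases under each scaling (median 0.60), including Col5a3 (0.98) and Col6a5 (1.49). Between the sugars edgeR called 0 of 16 (median 0.30), against 3 at an unadjusted p below 0.05 and 0 with DESeq2. Col4a6 was higher with high glucose too (0.49, edgeR adjusted p = 0.0471, against 0.58 with high fructose). With DESeq2 size factors in edgeR, 0 of 16 were called with high glucose. LPS had raised 3 and lowered 1, but raised 2 and lowered 3 with upper-quartile factors or library totals. The group holds Col1a1, Col1a2 and Col3a1 (1.83 to 2.02), fibroblast markers that were not called. Col1a1 had 59, 114 and 3 counts in the high-fructose libraries, and Col5a3 had 80, 121 and 122 there against 49, 59 and 63.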
